A study of Rattus norvegicus with 6 samples.

How the data were processed

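RNA of the renal cortex of 6 rats was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 3 for corn oil and 3 for carbon tetrachloride, per the labels. The scanner files hold the spot intensity as deposited by the authors, and per the file headers they were extracted with Agilent Feature Extraction 10.7.1.1 (version 10.7 per the submitters' processing notes). The processed signal in these files is a background-subtracted linear intensity per the file headers. The series' value table, deposited by the authors, is a linear intensity too: each column equalled the processed signal divided by 1 factor per array, between 1015 and 1092, close to that array's 75th percentile of signal, and the columns' medians were 0.118, 0.111 and 0.114 for corn oil replicates 1 to 3 and 0.116, 0.115 and 0.111 for carbon tetrachloride replicates 1 to 3. Scale and centring of the table follow from that comparison and no gene-wise centring was found, so none of scale, centring and direction stays unknown. The table has 0 columns of other samples.

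The main values are log2 of the processed signal minus each array's 75th percentile of it. The 1439 control spots were left out, as were spots with an outlier flag, of which an array had between 0 and 25, and 1 spot was saturated. Each non-control probe was spotted once. A probe was tested if it was well above background on all arrays of at least 1 group, which held for 42400 of 61537 probes. The files give an accession for each probe and no gene name column was used, so genes were named by matching the accession, without its version, to a table of RefSeq genes of the assembly GRCr8, used for names only. Of the probes 28206 (45.8%) matched, and the other 33331 kept the accession or probe name of the file. A gene or unmatched accession was represented by the tested probe of the highest mean over the 6 arrays, which gave 31193 tested transcripts. No coordinates are given, because the name table and the arrays rest on different genome builds. The plan had assumed a gene name column and a mean signal column. The normexp alternative therefore used the median spot signal with the median local background.

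The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the transcripts and a threshold of 0.05, and fold changes are treated minus control. The design text calls the samples biological replicates, so p-values measure the spread between rats. A probe well above background on 0 arrays of 1 group is given as at least N-fold: the mean of the brighter group against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. This bound rests on the main values and need not hold under another background correction. The 34 gene lists, written before the data were examined from general knowledge of kidney and toxicology, hold 923 genes, of which 798 were tested and 58 matched no probe. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists of at least 5 tested members, and also with an estimated correlation and with fry. The 24 transcripts with a missing value were left out of the list tests.

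The rule for named genes was written before the data were examined. With fewer than 10 transcripts past the threshold, it takes the 10 higher and 10 lower genes of smallest unadjusted p whose groups do not overlap, of each list up to 4 members past the threshold or else up to 2 with the smallest p, and 15 genes of injury, stress, drug metabolism and transport. Some genes that the rule takes are not given here.

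The code was tested on simulated data. Arrays were simulated with the real means of 31169 transcripts and the moderated spreads of the limma fit for this comparison. On the log2 scale, 95% of 100 transcripts changed by 2 and 63% of 100 changed by 1 were recovered. Of 30969 unchanged transcripts 8 were called. Moderation draws the spreads of transcripts together, and the planted changes ease the adjusted threshold. These shares are therefore no estimate of the power of the real comparison. The list test recovered a shifted list and called 0 of the 33 others. The simulated transcripts vary independently, so this does not test the preset correlation.

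The corn oil arrays and carbon tetrachloride replicates 1 and 2 lay on slide 1 and shared scan 1, and carbon tetrachloride replicate 3 lay alone on slide 2 in scan 2. On slide 1 the control arrays were in array row 1 and the treated arrays in row 2. Of 10 spike-in probes, the group means differed by -0.12 to 0.04 (log2). Alternatives were other background corrections and scalings, the deposited table, other filters, other ways to combine probes, an intensity trend with robust fitting, the replicate number or the slide as a block, the fit within slide 1 and the fit without each array. The slide block, the fit within slide 1 and the fit without carbon tetrachloride replicate 3 are the same fit.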

Results

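Gene expression was measured in the renal cortex of male Sprague-Dawley rats given carbon tetrachloride, a chlorinated solvent that cytochrome P450 enzymes turn into radicals and that is best known as a liver toxicant. Per the labels, 3 rats received 100 mg/kg/day for 4 weeks and 3 rats received corn oil, and the rats were 5 weeks old at purchase. The design text of the series names benzyl acetate as the treatment, whereas the title, the sample labels and the treatment protocol name carbon tetrachloride, which is used here. Each rat contributed 1 single-colour array, so the number of arrays limits the precision of each value. Between 68.5% and 72.1% of the 61537 non-control probes were well above background on each array, and 31193 transcripts were tested, of which 12328 carried a gene symbol. Correlations between arrays ran from 0.9917 to 0.9932 within the corn oil group, from 0.9914 to 0.9928 within the carbon tetrachloride group and from 0.9907 to 0.9937 between the groups.

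The comparison of carbon tetrachloride with corn oil asks which renal cortex transcripts differ after the treatment. Few differences passed their test. Of the 31193 transcripts, 1 passed an adjusted p of 0.05 in limma, and it was higher after carbon tetrachloride. It is the transcript XM_218564, which has no gene symbol here. It was well above background on the 3 treated arrays and on 0 of the control arrays, at -5.42 ± 0.04 against -7.99 ± 0.21 (log2 relative to the 75th percentile, mean ± SD, n = 3), so it was at least 1.44-fold higher, with an adjusted p of 0.0189. Its fitted log2 change of 2.58 meets the 2-fold condition but is set against signal below background, so a 2-fold change is not shown. No transcript passed in the lower direction. At an unadjusted p under 0.05 there were 1965 transcripts (6.30%), 1144 higher and 821 lower, where 1560 would come from chance alone and other splits of the same 6 arrays into 3 and 3 gave from 1076 to 2315. The fitted change was at least 2-fold for 263 transcripts (0.843%), 99 higher and 164 lower, including values set against signal below background. The 3 treated and 3 control values did not overlap for 12.8% of transcripts, where chance gives 10% for unfiltered values. The filter admits dim probes through 1 group, which favours such separation. This share was not computed for other splits, so an excess is not shown. With normexp on the median spot and background signals the log2 change of XM_218564 was 0.35 or 0.40 by normalization, and it was not called. Both values lie below the 1.44-fold bound, which holds for the main values only. The single call was absent in several other settings, among them the fit without carbon tetrachloride replicate 1 (adjusted p = 0.0984), without corn oil replicate 1 (0.309), and without carbon tetrachloride replicate 2 (0.175) or replicate 3 (0.172), the last of which lay alone on a second slide.

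**Figure D1:**
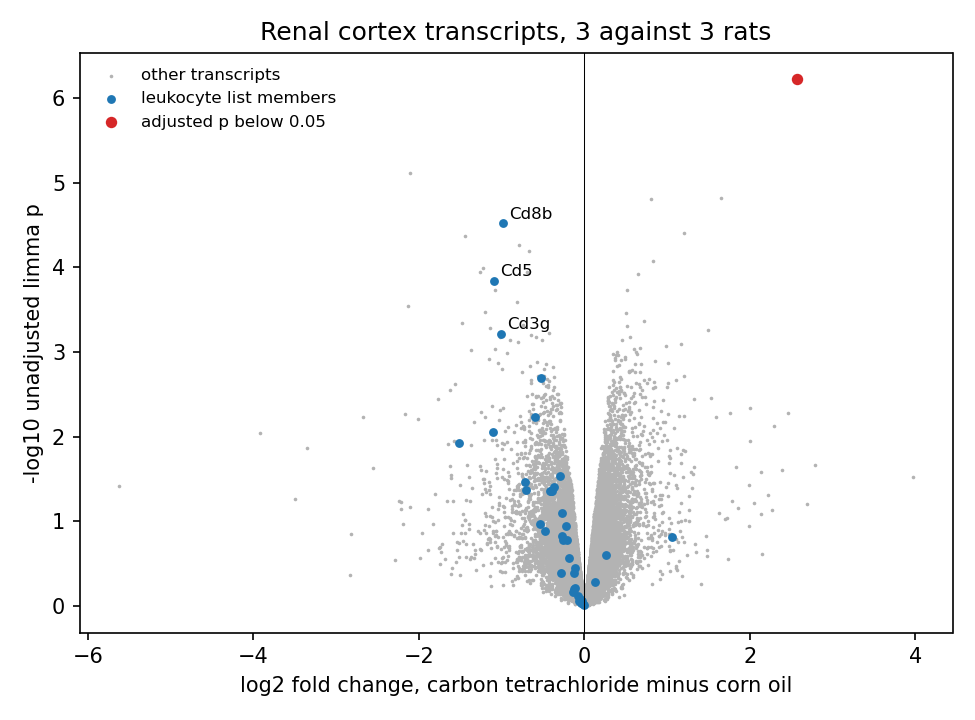
Each point is 1 of 31193 transcripts, with the log2 fold change (carbon tetrachloride minus corn oil) on the x axis and -log10 of the unadjusted limma p on the y axis; blue points are the 39 tested members of the leukocyte list and the red point is the 1 transcript with an adjusted p below 0.05. Of the blue points 36 lie left of 0 and 3 lie right of it.

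Among genes with a symbol, those of smallest p that separated the groups without overlap are given as values, since none passed the threshold. Cd8b, a chain of the CD8 co-receptor, had a log2 fold change of -0.98 ± 0.09 (SE, n = 3 per group), Cd247, a signalling chain of the T cell receptor complex, -0.79 ± 0.08, Cd3g, another chain of that complex, -1.01 ± 0.15, and Cd27, a co-stimulatory receptor of lymphocytes, -1.02 ± 0.16. Cd5, a receptor of T cells, and Tnfrsf17, a receptor of plasma cells, were not well above background on any treated array and were at least 1.73-fold and 1.69-fold lower there. Other lower values were those of Pmfbp1 at -1.26 ± 0.14, the cadherin gene Fat3 at -0.81 ± 0.10 and the receptor gene Gpr84 at -0.74 ± 0.11, well above background on 2 of the 3 treated arrays. The limma adjusted p of these genes ran from 0.187 for Cd8b to 0.627 for Cd27.

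On the higher side genes of smallest p were Lrit1, B3galt2, Upk3bl1, Or6b1, Tns1, Trim6, Spire2, Celsr2 and Map3k6, with limma adjusted p from 0.192 for Lrit1 to 0.689 for Map3k6. Lrit1 and the olfactory receptor gene Or6b1 were not well above background on the control arrays and were at least 1.64-fold and 1.47-fold higher on the treated arrays. The kinase gene Map3k6 had a log2 fold change of 0.86 ± 0.15, Upk3bl1 0.73 ± 0.10, B3galt2 0.51 ± 0.07 and Trim6 0.49 ± 0.09. Spire2, Tns1 and Celsr2 had 0.44 ± 0.08, 0.39 ± 0.07 and 0.37 ± 0.06.

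Of the 34 gene lists fixed before the data were examined, 4 passed an adjusted p of 0.05 in camera with its preset correlation of 0.01, 3 lower and 1 higher after carbon tetrachloride. Leukocyte markers fell, with 36 of 39 tested members lower, a mean log2 fold change of -0.31, a median of -0.25 and an adjusted p of 4.01e-10. No call holds with an estimated correlation: for this list the adjusted p = 0.900 with an estimated correlation, as it was for the other 3 lists, and fry called 0 lists in 1 direction. The list's mean lay 0.21, 0.38 and 0.35 below the control mean on the 3 treated arrays, but 1 of the control arrays lay 0.18 below it too. Without its T cell genes, a setting chosen after the values were seen, the list had a mean of -0.17 (adjusted p = 0.000156, and adjusted p = 0.900 with an estimated correlation). The 31 members left still held some genes of T or cytotoxic cells. Over all transcripts 0 members passed the threshold, and adjusted over the list alone 5 were lower: Cd8b, Cd5, Cd3g, Cd3d at -0.53 ± 0.10 and RT1-Da, a class II histocompatibility gene, at -0.60 ± 0.14. Within the slide that held both groups the mean shift of the list was -0.30.

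**Figure D2:**
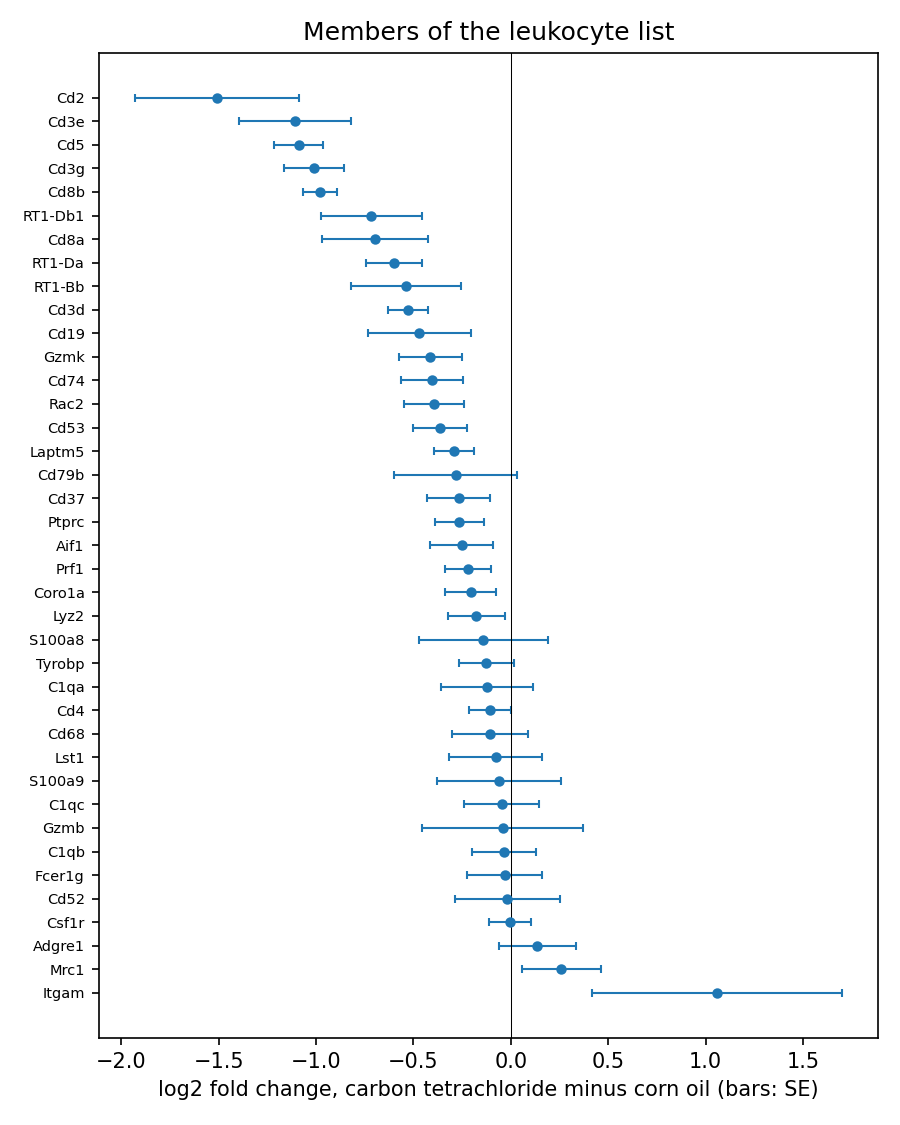
Log2 fold change (carbon tetrachloride minus corn oil, x axis) of each of the 39 tested leukocyte list members (y axis), with bars for the standard error of the limma fit from 3 rats per group. Cd2 lies lowest at -1.51 and Itgam highest at 1.06; Cd5, Cd2 and Cd3e were well above background on 0, 1 and 2 treated arrays and Itgam on 2 control arrays, so these are plotted at measured signals and not bounds.

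Values of the list's members, singled out after they were seen, are given without a test of a difference between cell types. Among T cell genes, Cd2 had -1.51 ± 0.42 (well above background on 1 treated array), Cd3e -1.11 ± 0.29 (on 2 treated arrays), Cd8a -0.70 ± 0.27 and Cd4 -0.11 ± 0.11, and Gzmb, a protease gene of cytotoxic cells, had -0.04 ± 0.41. The class II gene RT1-Db1 had -0.72 ± 0.26. Among genes of macrophages and other myeloid cells, Aif1 had -0.25 ± 0.16, Lyz2 -0.18 ± 0.15, Cd68 -0.11 ± 0.20, Csf1r -0.0053 ± 0.11, Mrc1 0.26 ± 0.20 and Itgam 1.06 ± 0.64 (well above background on 2 control arrays). The blood cell list, with 9 tested members, had a mean of -0.04 (adjusted p = 0.501 in camera).

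Cytokines and chemokines also fell, with 22 of 26 tested members lower, a mean log2 fold change of -0.34 and an adjusted camera p of 5.93e-07 (adjusted p = 0.900 with an estimated correlation). The members with the smallest p were Ccl5, a chemoattractant of T cells, at -0.57 ± 0.14 and Cxcl9, an interferon-induced chemokine, at -1.03 ± 0.25, and 0 members passed the threshold over all transcripts or adjusted over the list alone. On the slide that held both groups the shift was -0.30 on each treated array. Interferon-stimulated genes fell by a smaller amount, with 28 of 35 members lower, a mean of -0.11 and an adjusted camera p of 0.0257 (adjusted p = 0.900 with an estimated correlation). Rsad2, an antiviral gene, had -0.47 ± 0.16 and Cmpk2 -0.24 ± 0.10. This shift came mostly from carbon tetrachloride replicate 3, alone on the second slide: with the slide as a block, and so within the first slide, the mean was -0.026 (adjusted p = 0.649, against 1.09e-05 to 0.900 over all settings), and the call was also absent without corn oil replicate 1 (-0.039) or replicate 2 (-0.084).

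Endothelial markers rose slightly, with 13 of 15 members higher, a mean log2 fold change of 0.12 and an adjusted camera p of 0.0475 (adjusted p = 0.900 with an estimated correlation). Nos3, the nitric oxide synthase of endothelium, had 0.40 ± 0.07 and was the 1 member that passed adjusted over the list alone, and Tek, a receptor of angiopoietins, had 0.23 ± 0.08. The call was absent without corn oil replicate 1 (0.074), corn oil replicate 3 (0.13) or carbon tetrachloride replicate 1 (0.12) or 2 (0.12), and also with quantile normalization, median scaling, averaged probes or the replicate number as a block. It was present in 12 of 22 settings, a count in which the slide block, the fit within slide 1 and the fit without carbon tetrachloride replicate 3 are the same fit. Over all settings its adjusted p ran from 0.00115 to 0.900. With the slide as a block the mean was 0.13.

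**Figure D3:**
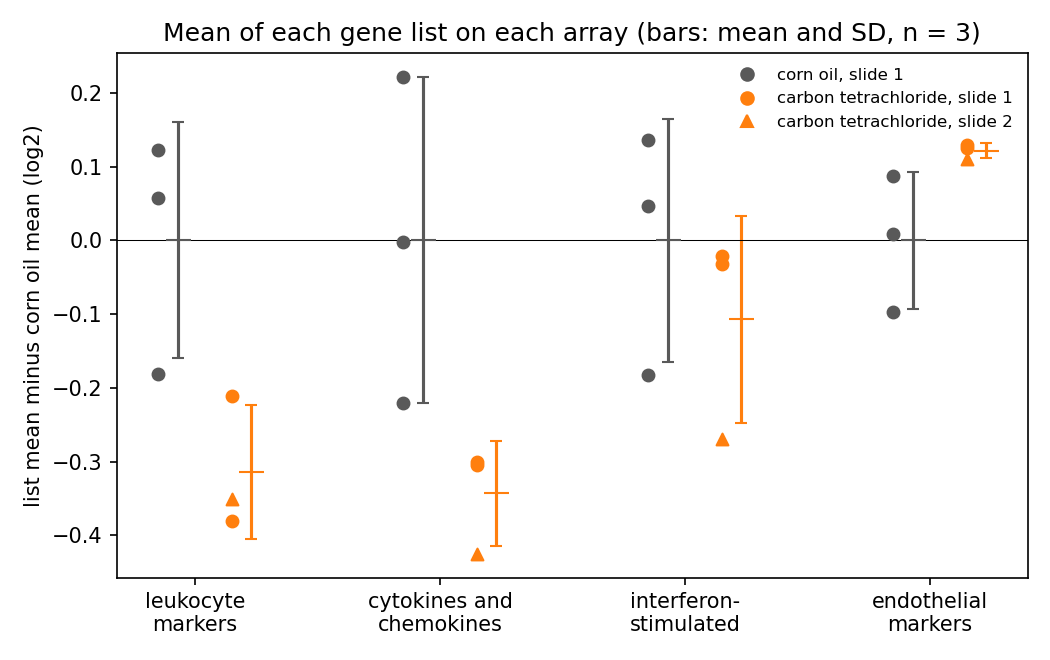
Mean of 4 gene lists on each of the 6 arrays as the difference from the corn oil mean (log2, y axis), for each list on the x axis; points are arrays, triangles mark the array on slide 2, and bars give the mean and SD of 3 arrays. The 3 treated arrays lie below the 3 control arrays for leukocyte markers and for cytokines and chemokines, while the groups overlap for interferon-stimulated genes.

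Markers of kidney injury showed no shared shift. The list, with 24 tested members, had a mean log2 fold change of -0.06 and an adjusted camera p of 0.795. Havcr1, which encodes the injury marker KIM-1, had -0.36 ± 0.27, Lcn2, which encodes NGAL, -0.47 ± 0.89, the osteopontin gene Spp1 -0.49 ± 0.40, Clu -0.25 ± 0.41 and Timp1 0.0073 ± 0.13. The values of Lcn2, Clu and Timp1 turned sign under some settings or without single arrays. Vim and Anxa2, the members with the smallest p, had 0.20 ± 0.09 and 0.19 ± 0.09. The NRF2 targets of the response to oxidative stress were not called, with 15 of 26 members higher, 11 lower and a mean of 0.03 (adjusted p = 0.686), and with Hmox1 at 0.08 ± 0.20, Nqo1 at -0.47 ± 0.28, Gclc at 0.25 ± 0.21 and Gstp1 at 0.40 ± 0.17. The p53 targets had a mean of 0.03 (adjusted p = 0.795), with Cdkn1a, which encodes a cell cycle inhibitor, at -0.0014 ± 0.07, Tp53inp1 at 0.39 ± 0.14 and Aen at 0.31 ± 0.17. Of the 3 probes of Cdkn1a, 1 had the direction of the named probe.

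Cytochrome P450 and conjugation enzymes, only some of which act on foreign compounds, showed no called change. Cytochrome P450s had a mean of -0.02 (camera, adjusted p = 0.686). Cyp2e1, the main activator of carbon tetrachloride, had -0.31 ± 0.14 and was lower on each treated array than on each control array, with a limma adjusted p of 0.798. Por, the reductase that serves P450 enzymes, had 0.28 ± 0.08, Cyp24a1 0.33 ± 0.24 and Cyp4a1 0.03 ± 0.14. Conjugation enzymes had a mean of 0.11 (adjusted p = 0.501), with Ugt8 at 0.50 ± 0.23. In lipid metabolism, fatty acid oxidation and PPARA targets had a mean of 0.0052 (0.995 as adjusted camera p), with Ucp2 at 0.34 ± 0.14. Cholesterol synthesis had a mean of 0.11 (0.501), with Dhcr7 at 0.23 ± 0.13. Fatty acid synthesis had a mean of 0.07 (0.501), with Gpam at -0.28 ± 0.06 and Fads2 at 0.34 ± 0.10, and it was among 4 lists called by fry for change in either direction (mixed adjusted p = 0.00938), with leukocyte markers (0.0116), cytokines and chemokines (0.0471) and podocyte markers (0.0478).

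Lists of nephron segments and transport were not called. Proximal tubule markers had a mean of 0.05 (camera, adjusted p = 0.600), with the endocytic receptor gene Lrp2 at 0.09 ± 0.09, Slc6a20a at 0.29 ± 0.13 and the glucose transporter gene Slc5a1 at -0.26 ± 0.14. Lrp2 and Slc5a1 each had 2 probes that differed in direction. Loop, distal and collecting duct markers had a mean of -0.01 (0.686), with Umod at 0.04 ± 0.20, Klk1 at -0.27 ± 0.09 and Aqp3 at 0.25 ± 0.11. Podocyte markers had a mean of 0.10 (0.212), with Nes at 0.38 ± 0.08 and Tcf21 at -0.51 ± 0.16. Nes was the 1 member past the threshold adjusted over the list alone, with a limma adjusted p of 0.689 over all transcripts. Angiotensin and kinin genes had a mean of 0.05 (0.686). Calcium, phosphate and vitamin D handling had a mean of -0.00016 (0.965), with the calcium channel gene Trpv6 at -0.79 ± 0.24, well above background on 2 of 3 treated arrays, and Atp2b1 at -0.14 ± 0.06. Gluconeogenesis and ammoniagenesis had a mean of 0.03 (0.686), with Got1 at -0.12 ± 0.09.

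Of the remaining lists, matrix and fibroblast genes had a mean of -0.07 (camera, adjusted p = 0.282), with Thy1 at 0.56 ± 0.12 and Thbs2 at -0.62 ± 0.14, and acute phase and complement genes -0.07 (0.473), with Cfb at 0.51 ± 0.27. Cell cycle genes had a mean of -0.05 (0.514), with the cyclin gene Ccnd1 at 0.72 ± 0.14 and Kif11 at -0.28 ± 0.12. Circadian clock genes had a mean of 0.14 (0.473), with Dbp at 0.67 ± 0.19 and Nr1d2 at 0.80 ± 0.27, and glucocorticoid-responsive genes 0.04 (0.995), with Fkbp5 at 1.17 ± 0.37 and Errfi1 at -0.59 ± 0.30. Endoplasmic reticulum stress genes had a mean of -0.0067 (0.501), with Asns at 0.46 ± 0.12 and Herpud1 at 0.31 ± 0.09, and heat shock genes -0.02 (0.466), with Hspb1 at 0.31 ± 0.08 and Dnaja1 at -0.23 ± 0.07. Immediate early genes had -0.04 (0.995), with Egr3 at 0.28 ± 0.08 and Dusp6 at -0.50 ± 0.16. The hypoxia response had -0.0043 (0.916), with Pdk1 at 0.35 ± 0.06 and Kdm3a, whose 2 probes differed in direction, at -0.14 ± 0.07. Pdk1 was the 1 member past the threshold adjusted over the list alone, with a limma adjusted p of 0.689 over all transcripts. Oxidative phosphorylation had -0.03 (0.212), with Cox7c at -0.24 ± 0.13 and Ndufa1 at -0.11 ± 0.06, and ribosomal proteins -0.02 (0.466), with Rpl14 at -0.09 ± 0.06 and Rps7 at -0.10 ± 0.07.

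Markers of tissues that dissection of the cortex might carry along were not called either. Adrenal gland markers had a mean of 0.09 (camera, adjusted p = 0.514), with Cyp11b3, whose 2 probes differed in direction, at 0.53 ± 0.27 and Scarb1 at 0.12 ± 0.09. Liver markers had 0.12 (0.694), with Apoa1 at 0.80 ± 0.24 and Hpx at 0.60 ± 0.21, and adipose markers 0.12 (0.501), with Cidea at 0.33 ± 0.13 and Retn, well above background on 2 of 3 control arrays, at 0.67 ± 0.35. Among blood cell markers Slc25a37 had -0.17 ± 0.07 and the platelet factor gene Pf4 -0.08 ± 0.11. Muscle markers had a mean of 0.03 (0.669), with Cnn1 at 0.40 ± 0.19, well above background on 1 of 3 control arrays, and Des at 0.23 ± 0.12. In 6 lists the median, the mean and the direction of the camera test were not all of 1 sign: kidney injury markers, cytochrome P450s, fatty acid oxidation, p53 targets, the angiotensin and kinin list and the calcium and phosphate list.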

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

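The settings without the RT1 genes and without the T cell genes were chosen after seeing the data. The count of 1 transcript past the threshold in limma, with or without the condition of a fitted 2-fold change, was 0 with normexp and either normalization, without a filter on dim probes, with the filter on all 6 arrays, which left it untested, with trend and robust fitting, with the replicate number or the slide as a block, and within slide 1. At an adjusted p of 0.10 it was still 1. Without single arrays the count ran from 0 to 2, with 0 to 1 higher and 0 to 1 lower, with or without the 2-fold condition: 0 without corn oil replicate 1 or carbon tetrachloride replicate 2 or 3, 2 without corn oil replicate 3, and without carbon tetrachloride replicate 1 another transcript, Gal, in place of XM_218564. Other settings kept XM_218564 as the 1 call. At an unadjusted p under 0.05 these settings gave between 1520 and 2323 transcripts, and 2712 of 42400 probes where each probe was tested alone. XM_218564, at least 1.44-fold higher in the main setting, had a log2 change of 0.35 and 0.40 with normexp, both below that bound. The cause of each loss was not tested.

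The 4 called lists became 7 with normexp and the 75th percentile, 8 with single probes, and 0 with an estimated correlation or with fry for change in 1 direction, while fry for either direction called 4. Without single arrays the number ran from 2, without corn oil replicate 1, to 5. Leukocyte markers (-0.31) and cytokines and chemokines (-0.34) stayed lower in each setting and lost their call only with an estimated correlation (adjusted p = 0.900 for both) and with fry (0.561 and 0.498). Leukocyte markers had a mean of -0.29 without the RT1 genes (adjusted p = 1.48e-08) and -0.17 without the T cell genes (0.000156), and for both the adjusted p = 0.900 with an estimated correlation. The 31 members of the latter setting still held some genes of T or cytotoxic cells. Endothelial markers (0.12) lost their call with quantile normalization (0.12), median scaling (0.13), averaged probes (0.12), the replicate block (0.12), an estimated correlation and fry, and ran from 0.074 to 0.17 without single arrays, with adjusted p from 0.00115 to 0.900 over all settings. Interferon-stimulated genes (-0.11) lost theirs without a filter on dim probes (-0.088), with averaged probes (-0.085), with the slide as a block and within slide 1 (-0.026), with an estimated correlation and with fry, and ran from -0.20 to -0.026 without single arrays, with adjusted p from 1.09e-05 to 0.900. The cause was not tested.

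Same-numbered rats did not deviate together (correlations of -0.023, -0.097 and -0.079). These values show no pairing by number, but a matching of small effect could be missed by them.

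Changes of sign were found 89 times among the results given here that were not called, and 0 of them passed the threshold. In parentheses is the main value, followed by the log2 values with another sign or the range. Cytochrome P450s (-0.023) gave 0.017 with single probes, 0.026 with the slide block and ranged from -0.12 to 0.059 without single arrays. Fatty acid oxidation and PPARA targets (0.0052) gave -0.025 with the slide block and ranged from -0.048 to 0.043 without single arrays. Loop, distal and collecting duct markers (-0.014) gave 0.032 with single probes, 0.024 with averaged probes, 0.017 with the slide block and ranged from -0.074 to 0.017 without single arrays. Cell cycle genes (-0.049) ranged from -0.16 to 0.086 without single arrays. Endoplasmic reticulum stress (-0.0067) gave 0.0027 with normexp and quantile normalization, 0.0028 with single probes, 0.0064 with the slide block and ranged from -0.037 to 0.011 without single arrays. Heat shock genes (-0.019) ranged from -0.065 to 0.030 without single arrays. Immediate early genes (-0.037) gave 0.052 with the slide block and ranged from -0.13 to 0.052 without single arrays. Glucocorticoid-responsive genes (0.041) ranged from -0.014 to 0.13 without single arrays. Angiotensin and kinin genes (0.047) gave -0.0090 with single probes and ranged from -0.065 to 0.13 without single arrays. Gluconeogenesis and ammoniagenesis (0.026) ranged from -0.0040 to 0.067 without single arrays. Calcium, phosphate and vitamin D handling (-0.00016) gave 0.031 with normexp and quantile normalization, 0.030 with normexp and the 75th percentile, 0.0042 with quantile normalization, 0.0052 with median scaling, 0.036 with the stricter filter, 0.011 with single probes, 0.0023 with averaged probes, 0.031 with the slide block and ranged from -0.026 to 0.031 without single arrays. Hypoxia response (-0.0043) gave 0.0011 with median scaling, 0.0098 with single probes, 0.00058 with averaged probes and ranged from -0.035 to 0.030 without single arrays. Ribosomal proteins (-0.021) ranged from -0.047 to 0.0017 without single arrays. Liver markers (0.12) gave -0.059 with single probes. Blood cell markers (-0.041) ranged from -0.21 to 0.16 without single arrays. Muscle markers (0.032) gave -0.0042 with the stricter filter, -0.0061 with averaged probes and ranged from -0.052 to 0.076 without single arrays.

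Among named genes those given here changed sign. Cyp11b3 (0.53) gave -0.17 with normexp and quantile normalization, -0.15 with normexp and the 75th percentile. Lcn2 (-0.47) ranged from -0.99 to 0.50 without single arrays. Clu (-0.25) ranged from -0.50 to 0.16 without single arrays. Timp1 (0.0073) gave -0.020 with normexp and quantile normalization, -0.030 with normexp and the 75th percentile, -0.070 with the slide block and ranged from -0.092 to 0.091 without single arrays. Hmox1 (0.077) ranged from -0.050 to 0.27 without single arrays. Cyp4a1 (0.030) gave -0.0023 with the slide block and ranged from -0.046 to 0.15 without single arrays. Cdkn1a (-0.0014) gave 0.021 with normexp and quantile normalization, 0.0089 with normexp and the 75th percentile, 0.0078 with quantile normalization, 0.0039 with median scaling, 0.21 with averaged probes, 0.044 with the slide block and ranged from -0.033 to 0.044 without single arrays. Lrp2 (0.087) gave -0.042 with averaged probes. Umod (0.041) ranged from -0.11 to 0.20 without single arrays. The cause was not tested for these.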

Other observations

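The tests on added gene lists, the slide, the other cell types and the probes seen in 1 group were chosen after the leukocyte result was seen; the counts over other splits of the arrays were planned. After the values of the leukocyte list's members were seen, 4 further lists were typed by lineage. T and NK cell genes outside the fixed lists had 31 of 36 tested members lower and a mean log2 fold change of -0.31, with Ctsw, a protease gene of cytotoxic lymphocytes, at -1.20 ± 0.29 (SE, n = 3 per group), Lat, an adaptor of T cell receptor signalling, at -0.65 ± 0.19 and Klrd1, a receptor of NK cells, at -0.47 ± 0.10, all singled out after their values were seen. MHC class II genes had 9 of 9 members lower and a mean of -0.42, with RT1-Db1 at -0.72 ± 0.26 (4 of its 5 probes in this direction) and Ciita, their transcriptional activator, at -0.42 ± 0.20, but carbon tetrachloride replicate 3 lay at 0.06 against the control mean and replicate 2 at -0.85. Macrophage and monocyte genes had a mean of -0.09 and B cell and lymph node genes -0.17. Adjusted over these 4 lists, camera with the preset correlation gave 2.78e-10 for T and NK cells, 0.00013 for MHC class II, 0.0242 for macrophages and 0.0658 for B cells. With an estimated correlation the adjusted p = 0.0517, 0.368, 0.545 and 0.373 in the same order. With fry the T and NK cell genes had an adjusted p of 0.0282, and 0.000423 for change in either direction. Some members had been seen before the lists were typed: 5 T and NK cell genes, and 4 MHC class II, 11 macrophage and 6 B cell genes that are in the fixed lists. Without them MHC class II had 5 of 5 members lower and a mean of -0.295 (adjusted p = 0.0821, and 0.556 with an estimated correlation), macrophages had a mean of -0.11 (0.0402, and 0.556 with an estimated correlation) and B cells -0.10 (0.452).

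A hypothesis is that the treated cortex held fewer T cell transcripts. Without the 5 genes seen before, 31 members had a mean of -0.257, between -0.26 and -0.25 on the treated arrays and between -0.16 and 0.12 on the control arrays, with an exact permutation p of 0.1, the smallest that 3 against 3 allows. The adjusted camera p was 8.54e-07 with the preset correlation and 0.0875 with an estimated one. These values go in the direction of the hypothesis. They come from the same arrays on which T cell genes had been seen to be lower, so they are no independent test and leave it undecided. The leukocyte shift did not rest on the slide of carbon tetrachloride replicate 3 alone. On the slide with both groups the mean was -0.296, with a standard error of 0.13. There, carbon tetrachloride replicate 1 lay at -0.21 and corn oil replicate 3 at -0.18 against the control mean. With so few arrays, and a criterion written after the result, a part played by the slide stays undecided. A general loss of leukocytes, which would lower macrophage genes as much as T cell genes, stays open: the shift of T and NK cell genes minus that of macrophage genes was -0.217 with a standard error of 0.11, and the groups overlapped, and without the genes seen before it was -0.145 with a standard error of 0.13. Lymphoid tissue attached to control samples stays open as well, with a difference from B cell and lymph node genes of -0.141 and a standard error of 0.13. Array row cannot be told apart from treatment on slide 1; carbon tetrachloride replicate 3, in row 1 of slide 2 like the controls of slide 1, had a leukocyte mean of -0.35 against the control mean, but on another slide.

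A leukocyte shift of nearly the size of the real one was found in another grouping. Among the 10 splits of the 6 arrays into 3 and 3, the real grouping gave the largest leukocyte mean, -0.314. The split that sets corn oil replicates 1 and 2 with carbon tetrachloride replicate 1 against the rest gave -0.297 and an adjusted camera p of 6.86e-11. It exchanges only corn oil replicate 3 and carbon tetrachloride replicate 1. Their list means lay close together, at -0.18 and -0.21 against the control mean, so a similar value follows. Any other split still sets some treated against some control arrays and so holds part of any treatment effect. In the remaining splits the mean lay between -0.193 and 0.139. The 4 called lists compare with up to 9 in another split, and 7 of 10 splits called at least as many. The 1 transcript past the threshold compares with up to 3 in another split, and 5 of 10 splits gave at least as many, with or without the 2-fold condition. Too few splits exist for a share under 0.05. The preset correlation of 0.01 lies below the estimated correlation of each called list. The estimate was 0.2 for leukocyte markers, 0.1 for cytokines and chemokines, 0.33 for interferon-stimulated genes and 0.17 for endothelial markers. Among the added lists it was 0.061 for T and NK cell genes and 0.51 for macrophage genes.

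There were 90 probes well above background on all 3 arrays of 1 group and on 0 of the other, 57 in the treated and 33 in the control group. The highest count in another split was 133, and 5 of 10 splits gave at least 90, too few splits for a share under 0.05.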
